A study of Rattus norvegicus with 2 samples.

How the data were processed

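Gene expression was measured in primary cultures of rat carotid body cells kept in normoxia (21% oxygen) or in chronic hypoxia (1% oxygen) for 7 days, with 16 carotid bodies per culture. Per the labels' protocols, RNA was amplified, reverse transcribed with 32P-labelled dCTP and hybridised to Atlas Rat 1.2 nylon membranes carrying 1185 genes. A phosphorimager recorded the membranes, and AtlasImage V2.0 quantified them, per the labels' protocols. Each of the 2 samples stands for 3 membranes, numbered 1 to 3. The labels call the membranes replicates and do not say whether each came from its own culture. All p-values therefore measure the spread between membranes, which may be technical.

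The deposited intensity values hold 1 linear brightness per gene and membrane, up to a ceiling of 65535. Their lowest values and medians lie far above 0, so background is included, and the membranes are not normalized to each other. A background column was not used here. The authors also made a table with 1 intensity per gene and condition, per the labels an average over the 3 membranes that was normalized to the average signal. Most of its entries are 0. The means of its columns are 1899 for normoxia and 1899 for chronic hypoxia, and the median of each is 0. How the authors took off background for that table, and the ratio and difference thresholds they used, are not given in the sources used here.

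From the membrane values, background was corrected with normexp and an offset of 50, log2 was taken, and the 6 membranes were quantile normalized, with limma 3.58.1 in R 4.3.3. A gene was tested where its intensity exceeded the membrane's 25th percentile on at least 3 of 6 membranes, which kept 1038 genes. That filter was fixed for files without a background column and passes many spots at background level. After the data were seen, a gene was called above background on a membrane where its intensity exceeded the membrane median by more than 3 times the spread of the values below the median. Intensities within 5% of the ceiling were counted as near the ceiling, where differences and SDs are not exact. This holds on normoxia membrane 3 also for Slc6a3, Cpe and Aldoa. Folds are given only for genes above background on at least 1 membrane of each group. For a gene above background in 1 group alone, a bound is given ("at least N-fold"), from the mean of the brighter group against the mean, over the dimmer group's membranes, of the higher of the gene's own value and the lowest value among genes above background. The brighter group's mean also takes in any of its membranes not above background, and there the bound is not a strict lower limit. Values are means of normalized log2 intensities, which understate changes of dim genes.

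Chronic hypoxia was compared with normoxia with lmFit and eBayes at default settings, group as the only term and Benjamini-Hochberg adjustment over the tested genes, called at an adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, over the 27 of 29 lists with at least 5 tested members, and with fry. Single genes of the nitric oxide synthase and endothelin list and levels per membrane were tested with two-sided exact permutation tests over the 20 assignments of the membranes, whose smallest p is 0.10. With 3 membranes per group the number of arrays limits the precision of every value. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

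The groups, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule names every nitric oxide synthase and endothelin gene on the array, up to 4 members of each list with the smallest p, the housekeeping genes, and the largest rises and falls past the threshold. Where fewer than 5 genes pass in a direction, it names the 5 with the smallest p. The text gives a part of the genes the rule takes, and that part was chosen after their values were seen. Other genes named in the text were chosen after their values were seen, and their sentences say so. The array's gene names are those of its design. A current symbol was assigned by hand to 455 of the 1185 genes from the deposited gene names, and each symbol was found in the rat RefSeq gene table of assembly GRCr8. Genes without a symbol keep the deposited name. A pair of symbols, Pdgfra and Kcnj11, has 2 spots each, and these were kept as separate genes. No genome coordinates are given, because the membranes are not tied to a build.

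The deposited values come in steps whose size differs between membranes: 51.5 on normoxia 1 and chronic hypoxia 1, 103 on normoxia 2, normoxia 3 and chronic hypoxia 2, and 44 on chronic hypoxia 3. These scan formats were treated as a technical batch, and for part of the genes and lists values are given within the first format, within the second format, or with the format as a block. Within the first format 1 membrane is compared with 1, and within the second 1 chronic hypoxia membrane with 2 normoxia membranes. Chronic hypoxia 3 is alone in its format, so it adds nothing to a difference with the format as a block.

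The fit was tested on simulated membranes of chronic hypoxia against normoxia, drawn from the measured background and signal with 200 genes changed by known folds. At the measured spread (a log2 SD of 0.80), with 1084 genes tested, the fit called 2 of 34 genes changed 2-fold, 4 of 28 changed 4-fold and 19 of 38 changed 8-fold among genes with signal above background, and 0 of 865 unchanged genes. Near background it called 0 of 33, 0 of 39 and 2 of 28. A simulated list of 25 genes shifted 2-fold, all with signal above background and varying independently, had a camera p of 7.8e-05. It does not show the power for lists of correlated genes or of genes mostly at background. At a log2 SD of 0.2, with 1072 genes tested, 0 of 35, 24 of 32 and 32 of 33 genes above background were called at the same folds, and 1 of 858 unchanged genes.

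Alternatives fixed in advance were no background correction, plain subtraction, offsets of 1 and 500, mean scaling, median centring, cyclic loess, no normalization, filters of none and all 6 membranes, the membrane number as a replicate block, moderation with trend and robust settings, membrane weights, leaving out each membrane, ratios of 1.5 and 3, camera with an estimated correlation, fry, and the authors' table. Chosen after the data were seen were a filter to genes above background on at least 3 membranes, the scan format as a block, and chronic hypoxia membranes 1 and 3 averaged and counted as 1 replicate.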

Results

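Cells of the carotid body, the arterial oxygen sensor at the carotid bifurcation, were profiled after 7 days in 21% or 1% oxygen, with 3 membranes per condition. The series asks how chronic hypoxia alters gene expression in these cells, in particular the nitric oxide synthase isoforms and the endothelin receptors. Median intensity was 2427, 3409 and 2681 on normoxia membranes 1 to 3 and 1704, 3409 and 16411 on chronic hypoxia membranes 1 to 3. The lowest intensity on chronic hypoxia membrane 3 was 14591, against 309 to 412 on the other 5 membranes. Genes above background numbered 161, 139 and 205 on the normoxia membranes and 165, 72 and 186 on the chronic hypoxia membranes. In all, 867 of the 1185 genes were above background on no membrane, 152 on at least 3 and 49 on all 6. Across genes, which are not independent replicates, rank correlations between membranes lay between 0.267 and 0.580 for 14 of the 15 pairs and at 0.772 for chronic hypoxia membranes 1 and 3.

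**Figure D1:**
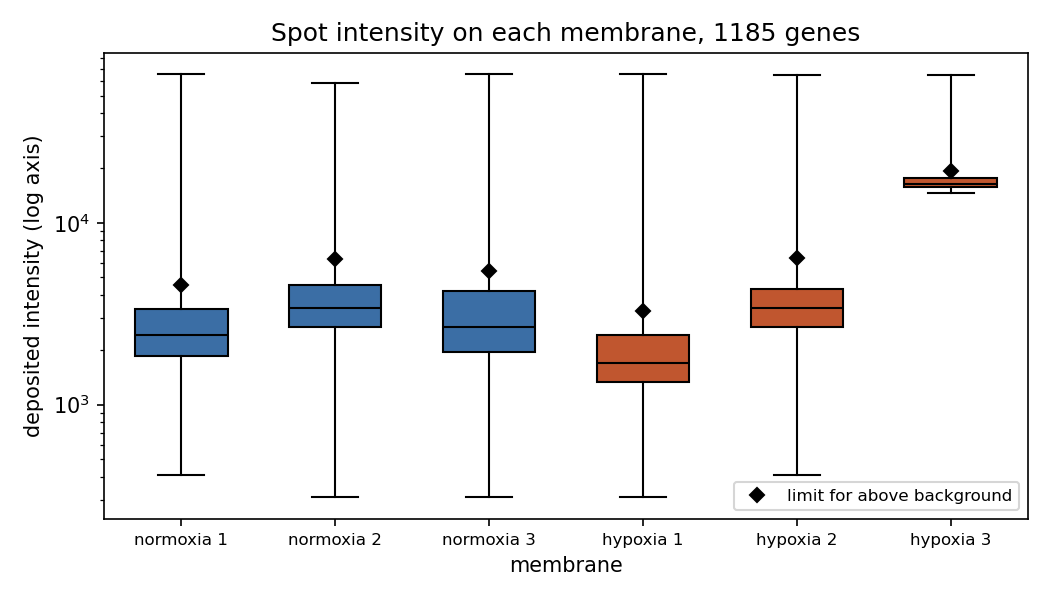
Deposited intensity of 1185 genes (log axis) on each of the 6 membranes (horizontal axis). Boxes span the quartiles with the median as a line, whiskers reach the lowest and highest values, and diamonds mark the limit for a gene above background, which is 19280 on chronic hypoxia membrane 3 and 3261 to 6406 elsewhere.

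Of genes marking the chemoreceptor (glomus) cells of the carotid body, Slc6a3, Dbh and Cpe were above background on all 6 membranes and the vesicular acetylcholine transporter Slc18a3 on 3. Slc6a3, the dopamine transporter, had a normalized log2 intensity of 15.30 ± 0.11 (SD, n = 3) in normoxia and 15.08 ± 0.29 (SD, n = 3) in chronic hypoxia. Dbh, which converts dopamine to noradrenaline, had 14.29 ± 0.43 (SD, n = 3) and 15.37 ± 0.27 (SD, n = 3). The Dbh spot lies directly beside that of acetylcholinesterase, the brightest gene on the array, and was dimmer than it on all 6 membranes. Spreading of signal into the Dbh spot was not tested. Cpe, a prohormone-processing enzyme of secretory granules, differed by a log2 value of -0.33 with an SE of 0.58. Slc6a3, Cpe, Slc18a3 and Mmp2 were named after their values were seen. Of 27 glomus cell genes on the array, 4 were above background on at least 3 membranes and 19 on none. Of markers of other cell types, Nos3 and Edn1 of the 8 endothelial genes and Mmp2 of the 11 fibroblast and matrix spots reached 3 membranes. Dbh was the member of the 6 sympathetic neuron genes that did. No member of the 9 glial, 7 immune, 2 erythrocyte and 1 smooth muscle genes did. Ribosomal protein genes were the most widely detected list, with 13 of 14 above background on at least 3 membranes.

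Of the 3 nitric oxide synthase isoforms, endothelial Nos3 was above background on all 6 membranes, inducible Nos2 on 4 and neuronal Nos1 on none. Levels of different spots are not comparable, so these counts do not rank the isoforms. Nos3 had a normalized log2 intensity of 15.67 ± 0.10 (SD, n = 3) in normoxia and 15.81 ± 0.08 (SD, n = 3) in chronic hypoxia. Its intensities on chronic hypoxia membranes 1 to 3, 65499, 64139 and 64448, all lay within 5% of the ceiling of 65535, as did normoxia membrane 3, so no fold is given (limma adjusted p = 0.961). Nos2 was 12.40 ± 1.46 (SD, n = 3) in normoxia and 14.17 ± 1.34 (SD, n = 3) in chronic hypoxia, a log2 difference of 1.77 with an SE of 0.88 (limma adjusted p = 0.645, exact permutation p = 0.2). It was above background on 2 of 3 membranes of each group. Within the first scan format the Nos2 difference was 0.75, within the second 1.07, and with the format as a block 0.93. In the second format Nos2 was above background on normoxia membrane 3 and not on normoxia membrane 2 or chronic hypoxia membrane 2. The 1.07 therefore rests on a chronic hypoxia spot at background. All of these differences leave out chronic hypoxia membrane 3, where Nos2 was highest (15.05).

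Endothelin-1 (Edn1), a vasoconstrictor peptide, and its converting enzyme (Ece1) were measurable, while both endothelin receptors, Ednra and Ednrb, were not above background on any membrane. Edn1 was above background on 1 normoxia and 2 chronic hypoxia membranes, with a log2 difference of 0.42 and an SE of 0.70 (limma adjusted p = 0.885, exact permutation p = 0.7). Without normoxia membrane 2 the Edn1 difference was -0.23, and within the scan formats it was 0.35 and -0.13. Ece1 had 14.98 ± 1.01 (SD, n = 3) in normoxia and 13.25 ± 1.20 (SD, n = 3) in chronic hypoxia, a log2 difference of -1.73 with an SE of 0.76 (limma adjusted p = 0.645, exact permutation p = 0.2). Ece1 was within 5% of the ceiling on 2 of 3 normoxia membranes, so -1.73 is not an exact difference. Its difference was -1.10 within the first scan format, -2.32 within the second and -1.80 with the format as a block. Of the 6 tested members of this list, 0 passed over all genes tested and 0 passed adjusted over the list alone, where the lowest adjusted p was 0.209. With membrane weights 1 member passed adjusted over the list alone.

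**Figure D2:**
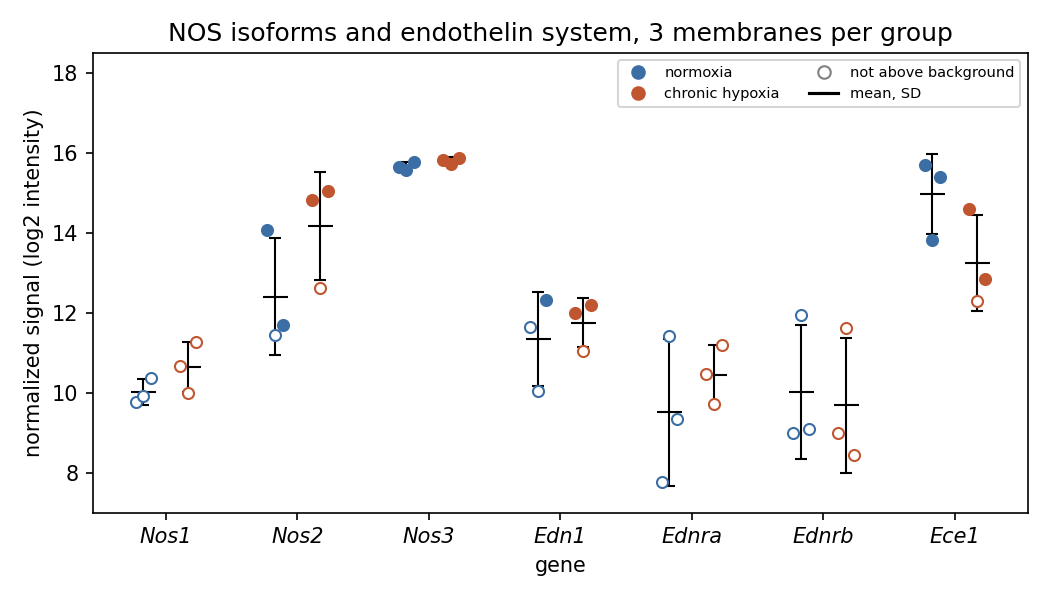
Normalized signal (log2 intensity, vertical axis) of 7 genes (horizontal axis) on 3 normoxia and 3 chronic hypoxia membranes. Points are membranes, open where not above background, and bars give the mean and SD; Ece1 is lower in chronic hypoxia by -1.73 and Nos2 higher by 1.77, with overlapping groups and with Ece1 near the ceiling on 2 normoxia membranes.

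Across the array no gene passed between chronic hypoxia and normoxia. In limma 0 of 1038 genes had an adjusted p under 0.05, the lowest was 0.630, and 75 genes had an unadjusted p under 0.05 (32 higher and 43 lower in chronic hypoxia) against 51.9 by chance. The 5 genes with the smallest p among those higher in chronic hypoxia, none of which passed, were preprolactin, the serotonin receptor Htr2c, a myristoylated alanine-rich protein, the metabotropic glutamate receptor Grm2 and neurexophilin 1. Those with the smallest p among genes lower in chronic hypoxia were annexin V, the merlin gene NF-2, the type IA receptor of bone morphogenetic proteins, and a pair of transporter genes, one for neurotransmitters and one for betaine. Of these 10 genes, 8 were above background on no membrane and have no fold. Htr2c was above background on 1 chronic hypoxia membrane (limma adjusted p = 0.630). Its bound of 1.24-fold higher in chronic hypoxia also takes in the other membranes of that group and is not a strict lower limit. The type IA receptor was above background on 2 normoxia membranes, and its bound was under 1.

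Genes with clear signal were examined separately, a choice made after the data were seen. Among the 152 genes above background on at least 3 membranes, 0 passed, 10 had an unadjusted p under 0.05, and the lowest limma adjusted p was 0.646. Rps3a, a component of the small ribosomal subunit, was 15.46 ± 0.20 (SD, n = 3) in normoxia and 13.50 ± 0.80 (SD, n = 3) in chronic hypoxia, a log2 difference of -1.95 with an SE of 0.59, and within 5% of the ceiling on normoxia membrane 3. Amphiphysin II, a membrane-bending protein, differed by -2.03 (SE 0.66) and liver arginase 1 of the urea cycle by -2.09 (SE 0.74). On the other side, mitochondrial chaperone Hspd1 differed by 1.55 (SE 0.63) and the testis form of the bifunctional enzyme of fructose 2,6-bisphosphate by 1.41 (SE 0.56). Proteinase activated receptor 2 was above background on the 3 chronic hypoxia membranes and on 0 normoxia membranes, at least 1.89-fold higher. Of the 152 genes 19 (12.5%), these 6 among them, had groups that did not overlap, against 10% by chance. The 10% takes the 6 membranes as exchangeable. It would be higher if the closely correlated chronic hypoxia membranes 1 and 3 were 1 replicate. Rps3a differed by -1.55 within the first scan format and -2.90 within the second, and Hspd1 by 1.39 and 0.77.

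Gene lists fixed in advance gave no shift past the threshold. The list nearest to it held receptors and enzymes of vasoactive and other peptides, with 23 of 28 tested members higher in chronic hypoxia, a median log2 difference of 0.46 and a camera adjusted p of 0.0533. With an estimated correlation its camera p was 0.0741 unadjusted and 0.999 adjusted. Every tested list had that same adjusted p, so it does not tell this list from the others. Of its 31 members on the array, 29 were above background on no membrane, among them Sstr5, Avpr2 and Bdkrb1. The median difference of the list was 0.30 within the first scan format and 0.94 within the second. With the format as a block the camera adjusted p was 0.0107, and without chronic hypoxia membrane 2 it was 0.969. For the other 26 lists the camera adjusted p was at least 0.593, no list passed with an estimated correlation, and the lowest adjusted p for a shift in one direction in fry was 0.155. Over all lists, 0 members passed over all genes tested and 0 passed adjusted over the list alone.

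Of 19 tested hypoxia-induced genes 12 were higher in chronic hypoxia, with a median log2 difference of 0.06 and a mean of 0.29 (camera adjusted p = 0.593). In fry, which tests whether the members move one way on balance, the unadjusted p was 0.00572 and the adjusted p 0.155. Of the 23 members on the array 15 were above background on no membrane, which may leave little power to show a shift. The power for such a list was not simulated. Its 4 members with the smallest p, Vldlr, Vegfa, Mif and Slc2a3, were above background on no membrane, except Mif on 1 chronic hypoxia membrane. Glycolysis genes were split, with 5 of 10 higher, a median of -0.04, a mean of 0.07 and a camera direction of up (adjusted p = 0.999). Aldoa and Aldoc, named after their values were seen, were above background on all 6 membranes and differed by 0.06 (SE 0.77) and 0.01 (SE 0.60), and both changed sign under other scalings and between the scan formats (0.36 and -0.48 for Aldoa, -0.59 and 1.01 for Aldoc). Slc16a1 and Pfkm were above background on no membrane and Hk1 on 1. Among 12 mitochondrial respiration genes, Atp5f1b, the catalytic subunit of ATP synthase, differed by -1.24 (SE 0.74), with -0.05 and -2.87 within the scan formats. Atp5pb was above background on 2 of 3 chronic hypoxia membranes, with a bound of 1.33-fold higher in chronic hypoxia. That bound is not a strict lower limit. Its highest value (13.06) came from chronic hypoxia membrane 2, where Atp5pb was not above background. Of 15 antioxidant genes 11 were lower in chronic hypoxia, Gpx3 by -1.43 (SE 1.10), with a list median of -0.40 (camera adjusted p = 0.706). Without chronic hypoxia membrane 2 the Gpx3 difference was -0.01.

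**Figure D3:**
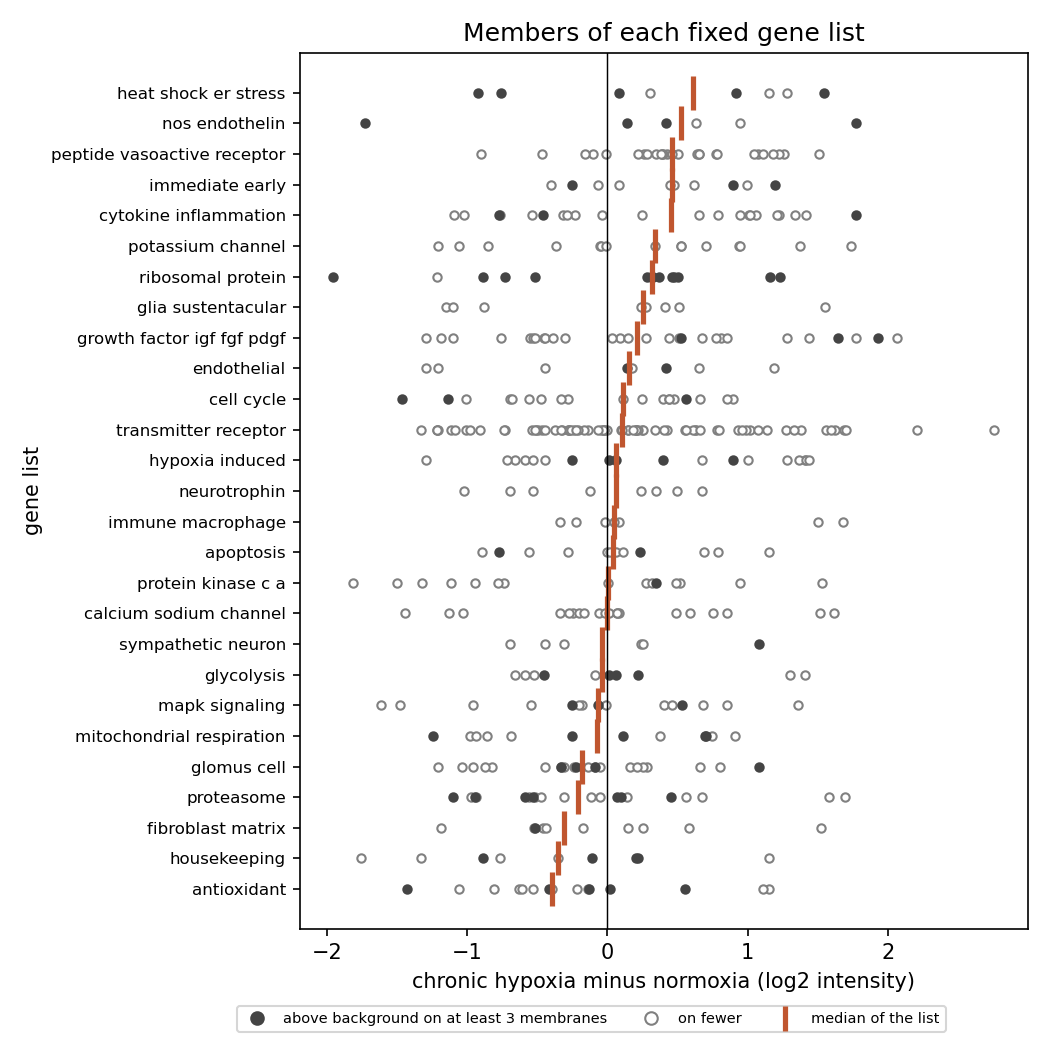
Log2 difference between chronic hypoxia and normoxia (horizontal axis) of the tested members of 27 gene lists (vertical axis). Filled points are genes above background on at least 3 membranes, open points genes on fewer, and bars list medians; peptide receptor members are open points with a median of 0.46.

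Stress and growth genes had members in both directions. In the heat shock list 6 of 8 members were higher in chronic hypoxia, with a median of 0.61 (camera adjusted p = 0.593). Its member Ddit3, a transcription factor of the stress response, differed by -0.93 (SE 0.66), with -0.24 and -0.48 within the scan formats. Of 10 immediate early genes 7 were higher, Arc by 1.19 (SE 0.68) and Jun by 0.90 (SE 0.88). Met, the hepatocyte growth factor receptor, differed by 1.93 (SE 0.87), with 0.24 within the first scan format and 1.99 within the second. Met was above background on both membranes of the first format and on none of the second, so 1.99 compares spots at background. Its growth factor list had 17 of 28 members higher. Cyclin B1 (Ccnb1) differed by -1.46 (SE 0.72), with -0.05 within the first scan format and -3.25 within the second. In the proteasome list 12 of 20 members were lower, Psma3 by -1.10 (SE 0.59). The immunoproteasome subunit Psmb9 had a bound of 1.67-fold higher in chronic hypoxia, above background on 2 of its membranes. That bound is not a strict lower limit, since it takes in chronic hypoxia membrane 2, where Psmb9 was not above background. Ribosomal protein genes went both ways, Rps12 by 1.23 (SE 0.62) and Rps19 by 1.16 (SE 0.55) against Rps3a, with a list median of 0.32, a mean of -0.01 and a camera direction of up. A change of ribosomal genes in either direction had a fry adjusted p of 0.0766. The median and the mean also differed in sign for the cell cycle, endothelial, glial, glycolysis, neurotrophin, protein kinase, calcium and sodium channel and sympathetic neuron lists, with the camera direction on the side of the mean. None of these genes or lists passed.

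Neural lists were mostly at background. Of the transmitter receptor, potassium channel, calcium and sodium channel and neurotrophin lists, 0 members were above background on at least 3 membranes, over 81, 21, 26 and 9 spots. Their median log2 differences were 0.10, 0.34, -0.01 and 0.06. The glomus cell list had a median of -0.18 (camera adjusted p = 0.706), with Dbh differing by 1.08 (SE 0.55, limma adjusted p = 0.645) and with 0.76 and 0.97 within the scan formats. Housekeeping genes had a list median of -0.35 (camera adjusted p = 0.593). Rps29, near the ceiling on 1 membrane of each group, differed by -0.89 (SE 0.97), with -2.82 within the first scan format and 1.46 within the second. Actb differed by -1.33 (SE 0.73), with 0.43 and -2.37 within the formats. Gapdh differed by 0.22 (SE 0.79) but by -0.05 without normalization and by 0.07 and -1.25 within the formats. Hprt1 differed by -0.11 (SE 0.81) but by 0.05 with cyclic loess and by 0.43 and -1.99 within the formats. Ywhaz, Odc1, Tuba1a and Pla2g1b were not above background on any chronic hypoxia membrane.

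Group means differed by at least 2-fold for 226 of the 1038 tested genes, 112 higher and 114 lower in chronic hypoxia. The values of the groups did not overlap for 102 of the 226. Without regard to size, 144 genes (13.9%) had groups that did not overlap, against 10% by chance. Among the 152 genes above background on at least 3 membranes, 18 were higher and 14 lower by at least 2-fold, and 15 of these had groups that did not overlap. Without normalization the tested genes split into 59 higher and 180 lower, and the median gene shifted by -0.17 on the log2 scale. No test goes with these counts.

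The authors' deposited table listed 132 genes above 0 in both conditions, 71 in normoxia alone, 121 in chronic hypoxia alone and 861 in neither. In the authors' deposited table Nos2 had 7134 in normoxia and 15197 in chronic hypoxia, a ratio of 2.13. No ratio is given for Nos3 and Ece1, which were near the ceiling on 4 and 2 membranes. The authors' deposited table listed Edn1 at 2518 in normoxia and at 0 in chronic hypoxia, Nos1 at 0 and 1330, and Ednra and Ednrb at 0 in both. Among genes above 0 in both columns of the authors' deposited table, 16 had a ratio of at least 2 and 12 a ratio of at most its inverse. The fit of the membranes had the same direction as the authors' deposited table for 87 of the 132 genes listed in both. Of the 121 genes the authors' deposited table listed in chronic hypoxia alone, 94 were above background on no chronic hypoxia membrane.

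Exact permutation tests of 3 against 3 membranes cannot pass 0.05, so the levels per membrane are given as values. The 25th percentile of intensity was 2166 ± 449 (SD, n = 3) in normoxia and 6568 ± 7923 (SD, n = 3) in chronic hypoxia (exact permutation p = 0.7, two-sided), with 1339, 2681 and 15683 on chronic hypoxia membranes 1 to 3. Mean intensity was 5098 ± 823 (SD, n = 3) and 8853 ± 8388 (SD, n = 3), with an exact permutation p of 1. Genes above background numbered 168 ± 33.6 (SD, n = 3) and 141 ± 60.7 (SD, n = 3), with an exact permutation p of 0.7.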

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

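The filter to genes above background, the scan format as a block and the membranes counted as 1 were chosen after the data were seen. No gene passed under any alternative except plain subtraction (18 genes, with dim values set to 1). Genes at an unadjusted p under 0.05, 75 as reported, numbered 31 where the 25th percentile was exceeded on all 6 membranes and 10 among genes above background on at least 3, where fewer genes were tested. With membrane weights they numbered 146, and with chronic hypoxia membranes 1 and 3 counted as 1, 46. Leaving out 1 membrane gave 42 to 105 of them, 0 genes that passed and 0 members of the nitric oxide synthase and endothelin list. The cause of these differences was not tested. That list had 1 member past the threshold with membrane weights and 0 otherwise. The peptide receptor list passed, as 1 list, with plain subtraction (camera adjusted p = 0.0103), mean scaling (0.0496), median centring (0.0386), no filter (0.0418), trend and robust moderation (0.0486), the scan format as a block (0.0107) and membranes 1 and 3 counted as 1 (0.0147). Its adjusted p was 0.0865 without background correction, 0.0997 with cyclic loess, 0.382 with the filter on all 6 membranes and 0.936 with membrane weights. It was 0.999 with an estimated correlation, as for every tested list, and 0.565 in fry. Leaving out 1 membrane it was 0.00551 to 0.969, which gave 0 to 1 lists. Among these it was highest without chronic hypoxia membrane 2 (0.969) and, next, without normoxia membrane 1 (0.355). The cause was not tested beyond the weighing given with the other observations.

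Genes with a 2-fold difference, 226 as reported, numbered 45 without background correction, 502 with plain subtraction, 124 with an offset of 500, 63 over the 25th percentile on all 6 membranes, 32 above background on at least 3, 481 at a ratio of 1.5, 57 at a ratio of 3 and 28 in the authors' values. Leaving out 1 membrane gave 212 to 249. With separate groups the 102 became 23, 61, 28 and 15 without background correction, at the offset of 500 and under the filters of all 6 and at least 3 membranes, and 117 to 175 leaving out 1 membrane, since fewer membranes separate more often. Without normoxia membrane 1 they were 157 and without chronic hypoxia membrane 2, 175. The hypoxia-induced list turned down with the 25th percentile exceeded on all 6 membranes (adjusted p = 0.953), the glomus cell list up with the same filter (0.870) and the antioxidant list up with membrane weights (0.980) and without chronic hypoxia membrane 2. The glycolysis list, up as reported, turned down without background correction (0.946), with plain subtraction (0.955), an offset of 500 (0.966), the filter on all 6 membranes (0.842) and trend and robust moderation (0.956), and without each membrane except chronic hypoxia 3. Leaving out 1 membrane, the adjusted p was 0.830 to 0.969 for glycolysis, 0.460 to 0.969 for antioxidant, 0.436 to 0.969 for glomus cell and heat shock and 0.273 to 0.969 for hypoxia-induced and housekeeping genes, and none passed under any alternative. The lists followed one by one were chosen after results were seen, and glycolysis was left out for a time after its turns were seen, then put back. Other lists were followed only in the count of lists. Signs turned for genes near 0: Aldoa with mean scaling (-0.052), median centring (-0.14), cyclic loess (-0.031), no normalization (-0.30), membrane weights (-0.18) and the scan format block (-0.12), Aldoc with median centring (-0.077), no normalization (-0.23) and membrane weights (-0.23), Gapdh with no normalization (-0.048), the scan format block (-0.68) and membranes 1 and 3 counted as 1 (-0.23), and Hprt1 without background correction (0.0078), with cyclic loess (0.053) and with membrane weights (0.73). Leaving out 1 membrane, Aldoa ranged from -0.58 to 0.76, Aldoc from -0.30 to 0.37, Gapdh from -0.41 to 1.21, Hprt1 from -0.73 to 0.91 and Edn1 from -0.23 to 0.84. With 1 membrane left out, sizes moved by more than 1.5 times, sign kept, for Ece1 (-2.36 to -1.14) and Rps3a (-2.37 to -1.25). So did those of Rps29 (-1.81 to -0.29), Actb (-1.80 to -0.63), Atp5f1b (-1.63 to -0.65), Ccnb1 (-1.83 to -0.80) and Gpx3 (-2.35 to -0.01). The same held for Ddit3 (-1.49 to -0.51), Slc6a3 (-0.37 to -0.11), Jun (0.12 to 1.54) and Arc (0.68 to 1.59). Over all alternatives Ccnb1 reached -3.60 and Atp5f1b -2.92, while Dbh, Rps12 and Met fell to 0.64, 0.63 and 1.24. The cause was not tested.

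Membranes of the same number deviated from their group means with correlations of 0.09, 0.11 and 0.02. For numbers 1 and 2 these were the highest of all pairs, while membrane 3 of each group correlated better with another number. Whether the number pairs the membranes was not tested. With the membrane number as a replicate block 0 genes passed and 83 had an unadjusted p under 0.05. No gene passed without the block either, so no call changed. A filter at 1 times the background was not run, because without a background column it is the filter used. Signal over background limits the data: the limit for a gene above background was 1.17 to 2.04 times the membrane median.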

Other observations

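Among the tests below, those with neighbouring background, rows and columns, dim spots beside bright ones and splits of the membranes were set before their results were seen, and the others after. Except for Dbh and Nos3, the genes in this paragraph were named after their values were seen. Of the 30 brightest genes 9 lay in row 10 of block C, among them acetylcholinesterase, 11-beta-hydroxysteroid dehydrogenase 2, carbonic anhydrases 4 and 5, mitochondrial aldehyde dehydrogenase 2, Dbh and Nos3. Of the 14 ribosomal protein spots none was at background on all membranes. A kinase kinase of calcium and calmodulin and the phosphatase SH-PTP2 were above background on the 3 normoxia membranes and 0 chronic hypoxia membranes, and proteinase activated receptor 2 the reverse.

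Nos3 shone beside a run of bright spots. Signal spreading from direct neighbours as the whole source of the Nos3 signal is argued against by the Nos3 spot being brighter than its brightest direct neighbour on 6 of 6 membranes. The ratio was 1.44 and 1.32 on normoxia membranes 1 and 2, where both spots lay below the ceiling, and is a lower limit elsewhere except on normoxia membrane 3 (1.01), where both were near it. Spreading into dim spots may occur: dim spots above or below a bright spot exceeded the other dim spots of their row on 6 of 6 membranes, by a median of 0.612 to 1.49 times the background spread. Values of dim genes beside bright ones, and of Dbh beside acetylcholinesterase, stay open to it. Neither a biological explanation for the run nor hybridisation of other transcripts was tested.

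Chronic hypoxia membranes 1 and 3 resembled each other more than any other pair. Over the 867 genes above background on no membrane their rank correlation was 0.590, against at most 0.310 for the other 14 pairs, which is in line with 1 preparation of labelled RNA or 1 membrane behind both scans. A gradient of background over rows and columns is argued against, since the correlation was 0.591 (95% bootstrap interval 0.541 to 0.633) after row and column medians were taken off, with the highest other pair at 0.267. A shared response to hypoxia stays open: over genes above background, membrane 2 correlated with membranes 1 and 3 at a mean of 0.533, against a mean of 0.576 across the groups, a difference of -0.04 with an interval from -0.13 to 0.05. Membrane 2 correlated at 0.613 and 0.637 with normoxia 2 and 3, which share its scan format, and at 0.542 with normoxia 1. With chronic hypoxia 1 and 3 it correlated at 0.578 and 0.487. The comparison therefore cannot separate scan format from hypoxia. If chronic hypoxia membranes 1 and 3 were 1 replicate, the fit would hold 46 genes at an unadjusted p under 0.05 in place of 75.

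The higher values of the peptide and vasoactive receptor list may rest on chronic hypoxia membrane 2. Without it the median log2 difference of the list was 0.31, within the range of -0.28 to 0.51 of 10000 random lists, while with all membranes it was 0.46, against -0.33 to 0.41. For a brighter area of the membrane around these spots, 76 tested genes beside the members had a median of 0.20 (95% bootstrap interval -0.03 to 0.34). That lies below the list and above the median of 0.03 over all tested genes. By the rule set before, it counts against the area as the whole cause. The rule gives the list median no interval, so the comparison cannot decide. More receptor transcript in hypoxia stays open, because 1 member was above background on at least 2 chronic hypoxia membranes, too few to decide.

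The 6 membranes make 10 splits of 3 against 3, too few for a share under 0.05. The real split is among the 10 and is itself included in each count of splits below. The real split gave 75 genes at an unadjusted p under 0.05, and 2 of 10 splits gave as many, the highest other 104. For genes with a 2-fold difference the real split gave 226, 2 of 10 gave as many, and the highest other gave 258. Both of these highest values came from normoxia 1 with chronic hypoxia 1 and 3 against normoxia 2, normoxia 3 and chronic hypoxia 2. That split follows the scan formats, with the second format on one side, and with the format as a block 60 genes had an unadjusted p under 0.05. The lowest camera adjusted p of a list was 0.0533 in the real split, 3 of 10 splits went as low, and the lowest other was 0.0138.

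The genes listed in chronic hypoxia alone in the authors' deposited table were hardly brighter on the membranes than the 861 genes listed in neither. Ranked by the 3 chronic hypoxia membranes, the area under the curve was 0.630 (95% bootstrap interval 0.578 to 0.683), and by the 3 normoxia membranes it was 0.671. For the 71 genes listed in normoxia alone, ranked by the normoxia membranes, it was 0.921. The authors' deposited table was also regressed on the unscaled membrane intensities, where an equal average of unscaled values would give weights near 1. Membranes 1 to 3 had 0.964, 1.35 and 0.755 in normoxia and 1.40, 1.73 and -0.0514 in chronic hypoxia. The weights have no interval, and closely correlated membranes such as chronic hypoxia 1 and 3 are poorly told apart. They therefore do not show which membranes the authors' average used. Gclc, an enzyme of glutathione synthesis named after its values were seen, stood in the authors' deposited table at 0 in normoxia and 14939 in chronic hypoxia, and was above background on the 3 normoxia membranes.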
